A study of Rattus norvegicus with 4 samples.

How the data were processed

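Gene expression was measured with 4 one-colour Agilent arrays of 60-base rat oligonucleotide probes, 2 for rats given saline and 2 for rats given liposomes, small vesicles of lipid. Per the labels, spleens of male WKAH rats were taken 24 h after the injection. Beads against MHC class II (antibody OX-6) first removed the cells that carry it, and beads against CD11b/c (antibody OX-42), an integrin of myeloid cells, then kept the cells that carry that. Total RNA of the remaining cells was extracted on columns, and 0.2 ug of it was amplified and labelled with the dye Cy3. The composition and dose of the liposomes were not given in the sources used here. The sample titles end in "exp" and the number 1 or 2, the same in both groups, without saying what this marks. The title numbers served as replicate names. The labels do not say that the arrays came from separate animals, so p-values measure only the spread between these samples, which may be technical.

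The deposited values are spot intensities on a linear scale. Per the submitters' processing notes, the arrays were read with Agilent Feature Extraction 10.7.3.1. Per the file headers, the processed intensity had its background and spatial trends removed within each array, with surrogate values for spots not above background, and was not scaled between arrays. The mean and local background intensities, also deposited, were used for 1 alternative. All 4 arrays lay on 1 slide and were read in 1 scan, so there was no slide or scan batch to test. The scanner software's own quality report had all metrics in range for liposome 1 and saline 2, 2 metrics out of range for saline 1 and 1 for liposome 2. On each array 61.3% to 66.3% of the 42877 spots other than controls were well above background, none was saturated, and 1.14% to 1.36% carried an outlier mark. For arrays, their number limits the precision.

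The design, the gene lists, the tests, the rule for naming genes and most alternatives were chosen before the data were examined. Control spots and spots marked as outliers were left out, spots of a probe were averaged, and each array's 75th percentile over all other probes was subtracted from the log2 processed intensity. Probes were kept when well above background on both arrays of at least 1 group, and 278 probes without a value on all 4 arrays were left out. The accessions of 18006 of 30367 probes matched the reference gene table, whose symbols were then used. Another 8186 probes kept the name given in the files, which can be old, and 4175 had no gene name and entered no gene-level test. For the 1834 genes with more than 1 passing probe, the brightest probe was used. Probe positions are those of the files, on the rat assembly rn4 (RGSCv3.4). No annotation of that assembly was used here, so exon or intron is not given.

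Log2 values of 12858 genes were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior of 2.26 degrees of freedom beside 2 residual ones), with data read through data.table version 1.17.8. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Log2 fold changes are liposome minus saline with their standard errors (SE) from limma, n = 2 arrays per group. An exact permutation test of 2 against 2 arrays cannot go below 0.333, so none was used. As a plain count without a test, genes were also counted whose groups lay at least 1 log2 unit apart, in the real and in both other splits of the arrays into pairs. A gene not well above background on either array of a group has only a bound there. The gene's rank and adjusted p come from the fitted fold and not from the bound. The spread behind that p rests partly on values not well above background. Its fold is given as "at least", the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the probe's own value and the lowest value of any probe well above background.

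The 27 gene lists, each with at least 5 measured genes, were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Benjamini-Hochberg adjustment was over the lists. None of the 10 calls held with an estimated correlation, where the smallest adjusted p was 0.651. In 20 simulated data sets of 12858 genes for liposome against saline, with 400 genes changed at each of 3 sizes, 76.2% of 2-fold, 95.1% of 4-fold and 98.2% of 8-fold changes were found, and 4.58% of the calls were false. A list of 20 genes shifted by 0.7 on the log2 scale was called in 20 of 20 simulations at the preset correlation. With an estimated correlation it was called in 0 of 20, so a miss there carries little information at this size. Simulated genes varied independently, though, while estimated correlations among the called lists reached 0.834, for interferon genes. The simulations therefore cannot show that calls at the preset correlation, or the share of false calls, hold for correlated genes.

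Named genes were the 12 with the largest rises and the 12 with the largest falls among genes with a proper symbol, past the threshold and with groups that did not overlap, then up to 4 members of each list with the lowest p, then Nos2, Arg1, Hmox1, Cd68, Itgam and RT1-Da whatever their values. This gave 135 genes, of which 83 passed the threshold. Not every gene that the rule takes is reported here. Genes outside the rule are said to be so where they appear. Alternatives changed the background correction, the scaling, the filter on dim probes, the treatment of several probes, the variance prior, the threshold, the unit counted, the list test, the use of title numbers as a block and the arrays included. Added after the data were seen were list medians within each title number and a fit without the T cell and natural killer cell lists.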

Results

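Expression was profiled in spleen cells depleted of MHC class II and enriched for CD11b/c, a fraction that the study title calls splenic macrophages, from rats given liposomes or saline 24 h earlier. The question was how gene expression in this fraction differed after liposomes were given. There were 2 arrays per group. The median processed intensity was 171 and 175 on saline 1 and saline 2, and 188 and 182 on liposome 1 and liposome 2. Across the 12858 genes tested, log2 values correlated at 0.989 between the saline arrays, at 0.993 between the liposome arrays and at 0.971 to 0.976 between arrays of different groups (genes are not independent replicates).

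As lists, genes of lipid handling and cholesterol efflux and of lysosomes lay higher on the liposome arrays, and genes of sterol synthesis, neutrophils, red cells and interferon response lay lower. These calls, made by limma's camera at a preset correlation, were lost with an estimated one (adjusted p = 0.651 to 0.866 with an estimated correlation). Fry also called the lipid, lysosome, sterol and red cell lists, but not the neutrophil and interferon lists (fry adjusted p = 0.0622 and 0.27). The lipid transporter gene Abca1 was 15.0-fold higher and the lysosomal glycoprotein gene Gpnmb 16.3-fold higher, while the macrophage gene Cd5l was 4.36-fold lower and the formyl peptide receptor gene Fpr3 11.5-fold lower. By limma, 1143 of 12858 genes passed the threshold, 621 higher and 522 lower on the liposome arrays, and 558 of them differed by 2-fold or more (346 higher, 212 lower). The groups lay at least 2-fold apart, with no overlap, for 429 genes (280 higher, 149 lower). Split by title number, the arrays lay so for 31 genes, and for 6 with the numbers crossed. Both other splits mix the groups on each side, so a gene whose groups do not overlap cannot be separated there. These counts are thus not a chance level for the 429. With median scaling 852 genes were higher and 442 lower. Without saline 1 or saline 2 limma called 499 and 372 genes. Without liposome 1 or liposome 2 it called 0 (smallest adjusted p 0.0558 and 0.0657, with 2177 and 2397 genes at unadjusted p under 0.05 against 4181 on all 4 arrays). There the remaining liposome array is assumed to vary as the saline arrays do, with 1 residual degree of freedom. Among the 83 named genes past the threshold, the fold or its bound moved by over 1.5 times for 4 with an array left out, and the fitted fold for 23 with normexp, which adds 50 to each signal and so lowers the folds of dim genes. Without the filter on dim probes limma called 0 of 21971 genes (smallest adjusted p 0.143, with 3005 at unadjusted p under 0.05).

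Genes of lipid handling and cholesterol efflux, many of them targets of the nuclear receptors LXR and PPARG, lay higher as a list. Of 23 measured members 14 rose, 1 fell and 8 did not pass, and 17 rose and 2 fell when adjusted over the list alone. The median log2 fold change was 1.07 (limma's camera, adjusted p = 1.69e-07, and adjusted p = 0.651 with an estimated correlation). Abca1, which moves cholesterol out of the cell, rose by 3.91 ± 0.14 log2 units (SE, limma adjusted p = 0.00752). Its probe lies on chromosome 5 at 70493613 to 70493672. Fabp5, a fatty acid binding protein, rose 14.5-fold and Pltp, the phospholipid transfer protein, 11.1-fold (log2 3.86 ± 0.15 and 3.48 ± 0.15, limma adjusted p = 0.00752 and 0.00757). Lpl, lipoprotein lipase, was not well above background on either saline array and was at least 6.89-fold higher (limma adjusted p = 0.00769, fitted log2 fold change 3.01, and 1.57 with normexp). Apoe and Nr1h3, outside the naming rule and picked after their values were seen, rose 12.7-fold and 4.24-fold. The single member that fell, also picked in this way, was Angptl4, an inhibitor of lipoprotein lipase (log2 -1.30). On the same arrays the erythroid and neutrophil lists lay lower, with median log2 fold changes of -0.84 and -0.73.

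Lysosomal genes lay higher as a list too. Of 26 measured members 11 rose, 0 fell and 15 did not pass, and 18 rose when adjusted over the list alone. The median log2 fold change was 0.74 (limma's camera, adjusted p = 1.04e-07, and adjusted p = 0.753 with an estimated correlation). Gpnmb rose by 4.02 ± 0.17 log2 units (limma adjusted p = 0.00752, probe on chromosome 4 at 77182198 to 77182257). The protease genes Lgmn and Ctsd rose 4.73-fold and 4.10-fold, and Hexa, a subunit of beta-hexosaminidase, rose 4.18-fold (log2 SE 0.14, 0.11 and 0.11, limma adjusted p = 0.00892, 0.00799 and 0.00769). Cd68, a glycoprotein of macrophage lysosomes, lay at 0.76 ± 0.15 log2 units (limma adjusted p = 0.054). The erythroid and neutrophil medians of -0.84 and -0.73 were measured on the same arrays.

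Genes of sterol biosynthesis and LDL uptake, targets of SREBP2, lay lower as a list by small amounts. Of 23 measured members 8 fell, 0 rose and 15 did not pass, and 11 fell when adjusted over the list alone. The median log2 fold change was -0.37 (limma's camera, adjusted p = 0.000135, and adjusted p = 0.753 with an estimated correlation). Squalene epoxidase (Sqle) was 1.91-fold lower, and Idi1, Msmo1 and Cyp51 were 1.72-, 1.66- and 1.59-fold lower (limma adjusted p = 0.0206, 0.0351, 0.0335 and 0.0345). Idi1 had an adjusted p of 0.0538 with median scaling. The erythroid and neutrophil lists moved the same way on these arrays, with medians of -0.84 and -0.73.

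**Figure D1:**
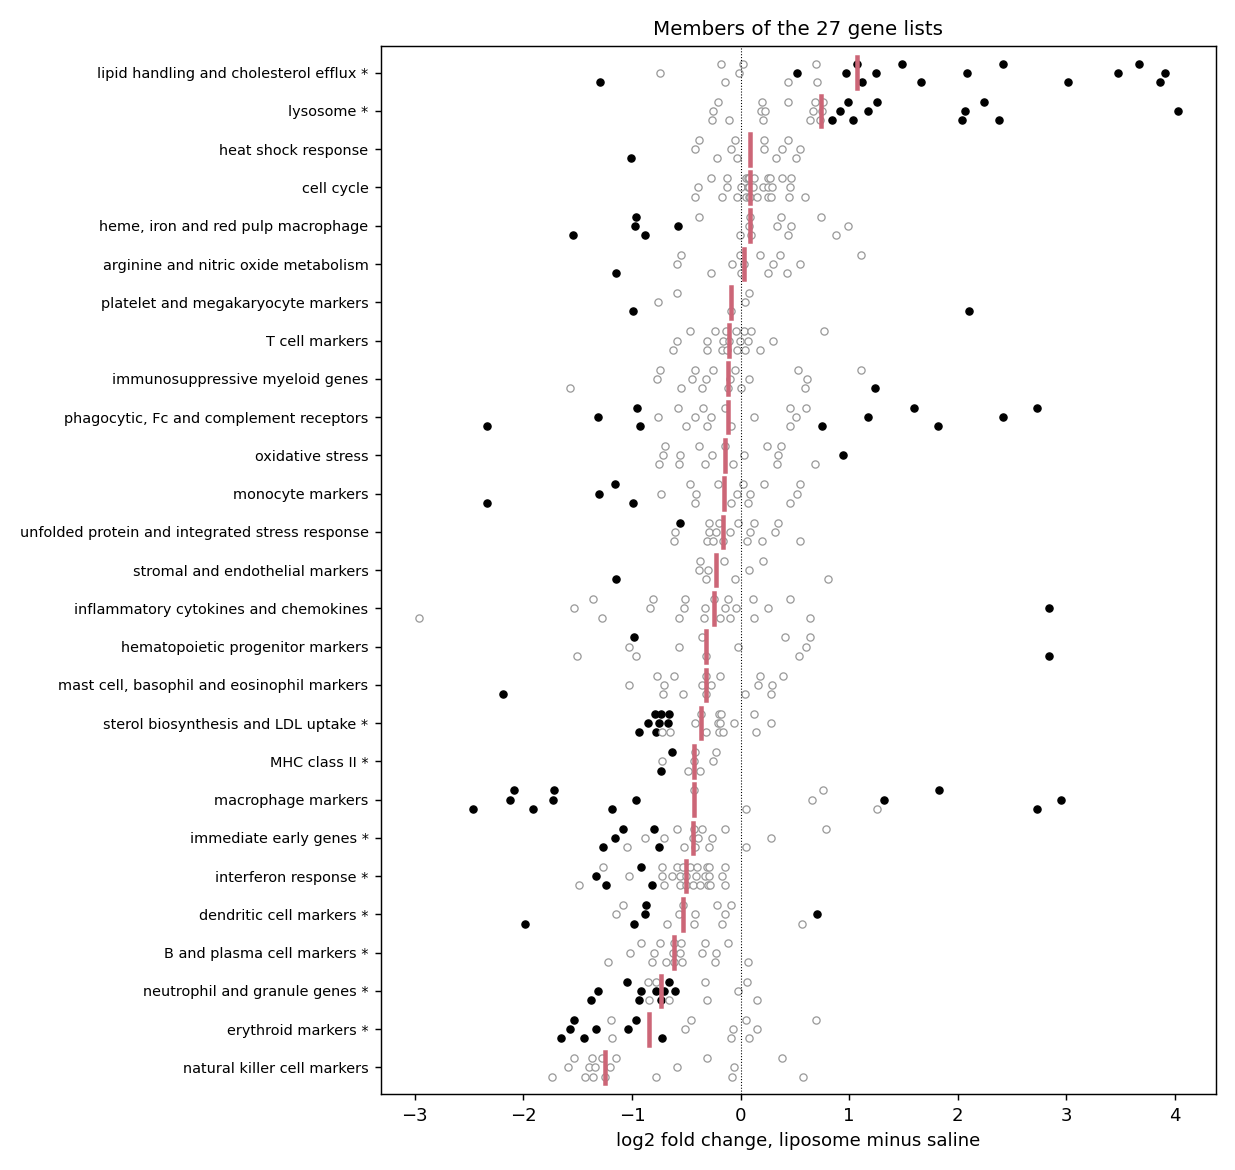
Each circle is a measured gene of the 27 lists, placed by its log2 fold change (liposome minus saline, 2 arrays per group), filled where limma's adjusted p was under 0.05, with a red bar at the list's median and a star at lists called by limma's camera at the preset correlation. Lipid handling (median 1.07) and lysosome (0.74) lie highest and the uncalled natural killer cell list (-1.25) lowest.

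**Figure D2:**
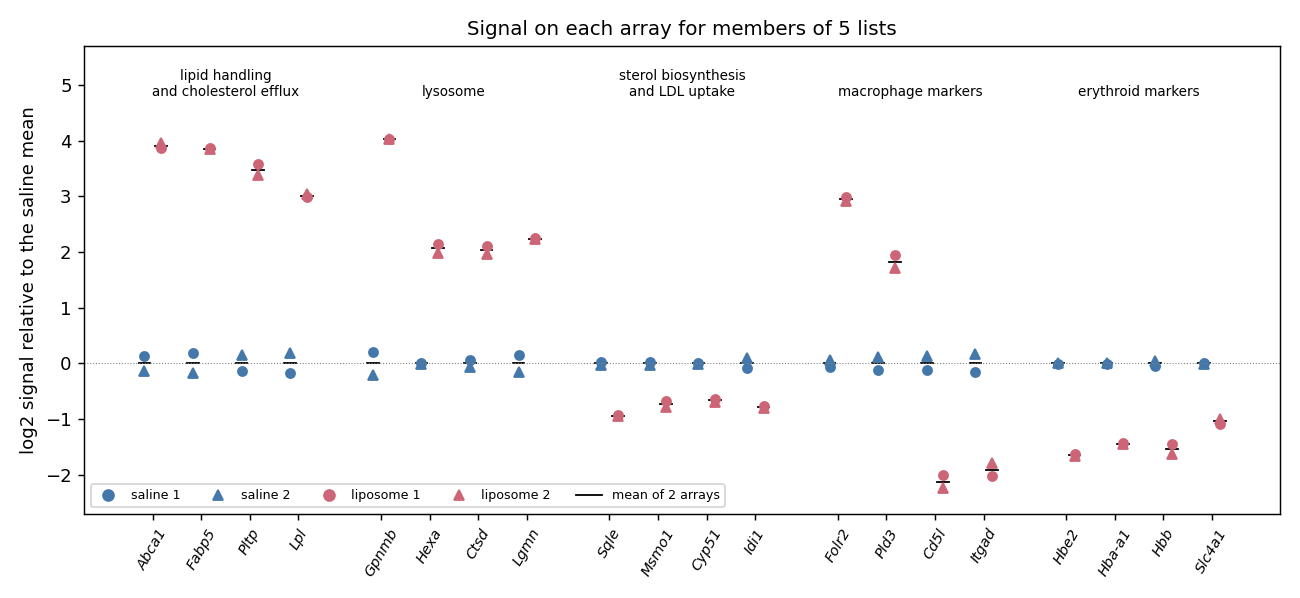
Log2 signal of each array relative to the mean of both saline arrays, for the 4 members with the lowest p of 5 lists (blue saline, red liposome, circle number 1, triangle number 2, line the mean of 2 arrays). For these genes the liposome arrays lie together and apart from the saline arrays, which the choice by lowest p favours. The liposome mean is 3.91 for Abca1 and -0.94 for Sqle, and Lpl was not well above background on the saline arrays.

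The 12 genes named for the largest rises lay outside the 27 lists. Mmp14, a membrane-bound metalloproteinase, rose 49.2-fold (log2 5.62 ± 0.14, limma adjusted p = 0.00752, probe on chromosome 15 at 32503002 to 32503061). Mmp12, macrophage elastase, rose 65.0-fold and Fabp3, a fatty acid binding protein, 46.0-fold by the fit, each well above background on 1 of 2 saline arrays (limma adjusted p = 0.00769 and 0.0198). The chemokine gene Ccl9 rose 42.1-fold (limma adjusted p = 0.00752), and Flvcr2, a transporter of the cell membrane, 18.9-fold (limma adjusted p = 0.0207). For Fabp3 the log2 fold change was 5.52 on all arrays and 4.76 without saline 2, where the gene was not well above background. For Flvcr2 it was 4.24 on all arrays, 4.85 without saline 1 and 3.62 without saline 2. The other 7 were not well above background on the saline arrays, so their folds are bounds. Their rank and adjusted p come from the fitted folds. Stac2 was at least 23.1-fold higher, Plau, urokinase, at least 21.1-fold, Mmp7 at least 20.1-fold, and Spp1, osteopontin, at least 15.4-fold (limma adjusted p = 0.00752, 0.00757, 0.00897 and 0.00897). Mgll, monoglyceride lipase, was at least 11.3-fold higher, Wt1 at least 7.14-fold and Eya4 at least 7.07-fold (limma adjusted p = 0.00752, 0.0335 and 0.0243). With normexp the log2 fold changes of the 12 genes ran from 1.85 to 5.30.

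Of the 12 genes named for the largest falls, 4 were well above background on all 4 arrays. Defb14, a beta-defensin, fell 13.3-fold, Fpr3 11.5-fold, Cdh1, E-cadherin, 9.57-fold and Capn3, a calpain protease, 8.16-fold (limma adjusted p = 0.00757, 0.00769, 0.00752 and 0.00752). The Cdh1 probe lies on chromosome 19 at 36511853 to 36511912. The other 8 were not well above background on the liposome arrays. They were ranked by fitted folds, and the adjusted p given belongs to those folds and not to the bounds. Prss21 was at least 7.10-fold lower, Npas4, an activity-induced transcription factor gene, at least 4.43-fold, Pdgfrl at least 3.83-fold and Efhb at least 3.35-fold (limma adjusted p = 0.0497, 0.0216, 0.0229 and 0.0152). Pla2g5, a secreted phospholipase, was at least 2.53-fold lower, the sulfotransferase gene Sult1a1 at least 2.44-fold, Ppl, periplakin, at least 2.31-fold and the olfactory receptor gene Or1a1b at least 1.85-fold (limma adjusted p = 0.016, 0.0386, 0.0366 and 0.0216). Prss21, Sult1a1 and Ppl missed the threshold with quantile normalization (limma adjusted p = 0.0524, 0.0514 and 0.0545), and Prss21 also with the mean of a gene's probes (0.0503). Without saline 1 or saline 2 the bound was 3.81 and 1.56 for Sult1a1 and 3.58 and 1.49 for Ppl, and with normexp the log2 fold changes of the 12 genes ran from -3.56 to -1.10.

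Macrophage markers moved in both directions. Of 17 measured members 4 rose, 8 fell and 5 did not pass (7 rose and 8 fell when adjusted over the list alone), and limma's camera gave no call (median log2 fold change -0.43, mean -0.18, adjusted p = 0.713). The median was -0.19 without saline 1 or with probes above background on all arrays, and -0.14 without the filter on dim probes. Folr2, a folate receptor of tissue macrophages, rose 7.74-fold and Pld3 3.54-fold, while Cd5l fell 4.36-fold and the integrin gene Itgad 3.76-fold (limma adjusted p = 0.00752, 0.0139, 0.0118 and 0.016). The other risen members, picked after their values were seen, were Mertk, a receptor for dying cells, at least 6.38-fold higher (fitted log2 fold change 2.73, and 1.47 with normexp), and its ligand gene Gas6 (log2 1.32). The other fallen members, picked in the same way, were C1qa, C1qb and C1qc (log2 -1.73, -1.71 and -2.09), Axl, Slco2b1 and Cd163. Axl lay at -1.18 (-0.59 with normexp), and Slco2b1 was at least 2.84-fold lower (fitted log2 fold change -2.46, and -0.88 with normexp). Among genes of heme, iron and red pulp macrophages 5 of 17 fell, 0 rose and 12 did not pass (4 rose and 5 fell when adjusted over the list alone), with no call by limma's camera (adjusted p = 0.842). Their median was 0.08 and their mean -0.05, and camera's direction was up. Vcam1 fell 2.91-fold, transferrin (Tf) 1.96-fold, haptoglobin (Hp) 1.84-fold and the iron exporter gene Slc40a1 1.49-fold, and Cd163, picked after its value was seen, fell by 0.96 on the log2 scale (limma adjusted p = 0.0272, 0.0338, 0.0287, 0.0468 and 0.0494). Tf missed the threshold with quantile normalization (0.0556) and Slc40a1 with median scaling (0.0613). Hmox1, heme oxygenase, lay at -0.38 ± 0.16 log2 units (limma adjusted p = 0.18).

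Phagocytic, Fc and complement receptors also went both ways. Of 24 measured members 6 rose, 4 fell and 14 did not pass (8 rose and 8 fell when adjusted over the list alone). The median was -0.11 while the mean was 0.15 and camera's direction was up, without a call (adjusted p = 0.741). The scavenger receptor genes Msr1 and Scarb1 rose 5.35-fold and 3.52-fold and the lipid receptor gene Trem2 3.02-fold, while the Fc receptor gene Fcgr3a fell 5.06-fold (limma adjusted p = 0.0153, 0.0152, 0.0133 and 0.00837). The others that fell, picked after their values were seen, were C3 and the C-type lectin genes Clec4d and Clec4e (log2 -1.31, -0.92 and -0.95). Of 18 measured monocyte markers 4 fell, 0 rose and 14 did not pass (6 fell when adjusted over the list alone), with a median of -0.15 (limma's camera, adjusted p = 0.15, and 0.0203 without saline 2). They were Fcgr3a, the chemokine receptor genes Ccr2 and Cx3cr1, 2.47-fold and 1.99-fold lower, and Nr4a1, 2.23-fold lower (limma adjusted p = 0.0495, 0.0361 and 0.0371). Ccr2 missed the threshold with quantile normalization (0.0559) and with the mean of a gene's probes (0.0502). Itgam, which encodes CD11b, part of the antigen used for enrichment, lay at 0.46 ± 0.22 log2 units (limma adjusted p = 0.225).

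Markers of other spleen cells differed between the groups. Of 18 measured erythroid markers 8 fell, 0 rose and 10 did not pass (11 fell when adjusted over the list alone), with a median log2 fold change of -0.84 (limma's camera, adjusted p = 0.000126, and adjusted p = 0.651 with an estimated correlation). That median was -0.50 with normexp and -0.51 without the filter on dim probes. The globin genes Hbe2, Hbb and Hba-a1 fell 3.14-, 2.89- and 2.71-fold and the anion exchanger gene Slc4a1 2.06-fold (limma adjusted p = 0.00837, 0.0131, 0.00978 and 0.0189). Of 19 measured neutrophil and granule genes 10 fell, 0 rose and 9 did not pass (15 fell when adjusted over the list alone), with a median of -0.73 (limma's camera, adjusted p = 2.74e-06, and adjusted p = 0.753 with an estimated correlation). Cd177 and Ngp fell 2.59-fold and 2.48-fold, Slpi 1.91-fold and S100a8 1.72-fold (limma adjusted p = 0.0224, 0.016, 0.0304 and 0.0299). Of 19 measured B and plasma cell markers 18 lay lower, yet 0 passed over all genes and 7 fell when adjusted over the list alone, with a median of -0.61, and of -0.40 without liposome 2 (limma's camera, adjusted p = 0.000135, and adjusted p = 0.866 with an estimated correlation). Blk, Mzb1 and Ebf1 had log2 fold changes of -0.91, -0.82 and -0.54 (limma adjusted p = 0.0612, 0.0712 and 0.075).

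Dendritic cell markers and MHC class II genes, whose product was the target of the depletion step, lay lower as well. Of 17 measured dendritic cell markers 4 fell, 1 rose and 12 did not pass (10 fell and 2 rose when adjusted over the list alone), with a median log2 fold change of -0.53 (limma's camera, adjusted p = 0.003, and adjusted p = 0.651 with an estimated correlation). The lectin gene Clec10a fell 3.97-fold, the cytokine receptor gene Flt3 1.98-fold and Tcf4 1.83-fold, and the adhesion gene Cadm1 rose 1.63-fold (limma adjusted p = 0.0193, 0.0267, 0.0432 and 0.0494). The fourth to fall, picked after its value was seen, was Batf3 (log2 -0.88, limma adjusted p = 0.0495). Cadm1 missed the threshold with quantile normalization (0.0504) and with the mean of a gene's probes (0.0503). All 9 measured MHC class II genes lay lower, 2 fell, 0 rose and 7 did not pass (6 fell when adjusted over the list alone), with a median of -0.43 (limma's camera, adjusted p = 0.00155, and adjusted p = 0.866 with an estimated correlation). RT1-DOa and RT1-Db1 fell 1.66-fold and 1.55-fold (limma adjusted p = 0.0425 and 0.045), RT1-Db1 not with quantile normalization (0.0736). RT1-DOb, RT1-Bb and RT1-Da had log2 fold changes of -0.72, -0.49 and -0.42 (limma adjusted p = 0.052, 0.0692 and 0.0904).

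T cell and natural killer cell genes followed the title numbers in both groups. The median natural killer gene was higher on number 2 than on number 1 by 1.54 log2 units among saline arrays and by 1.58 among liposome arrays, and the median T cell gene by 1.29 and 0.90. Of 19 measured natural killer cell markers 17 lay lower on the liposome arrays and 0 passed, also when adjusted over the list alone, with a median log2 fold change of -1.25 (limma's camera, adjusted p = 0.0537, and adjusted p = 0.947 with an estimated correlation). Under each other scaling, filter and probe rule the list was called (adjusted p = 0.0143 to 0.0483). The median difference was -1.11 within number 1 and -1.21 within number 2. The median log2 fold change was -2.08 without saline 1, -2.00 without liposome 2, -0.43 without liposome 1 and -0.44 without saline 2. These left-out fits have the title numbers uneven between the groups, so they mix the difference by number with that by group. The lectin-like receptor genes Klrb1b and Klrk1 had log2 fold changes of -0.78 and -0.31, Gzmk -1.74 and Ccl5 -1.54 (limma adjusted p = 0.0771, 0.208, 0.261 and 0.265). For Klrk1 the other passing probe lay at -1.01. Of 21 measured T cell markers 0 passed, also when adjusted over the list alone, with a median of -0.11 (limma's camera, adjusted p = 0.846). The T cell median was -0.64 without saline 1, and it lay above 0 without liposome 1 or saline 2 (0.39 and 0.55), again with uneven numbers. Thy1, Lef1, Foxp3 and Cd8b had log2 fold changes of -0.46, 0.76, 0.30 and -0.23 (limma adjusted p = 0.189, 0.225, 0.396 and 0.398).

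**Figure D3:**
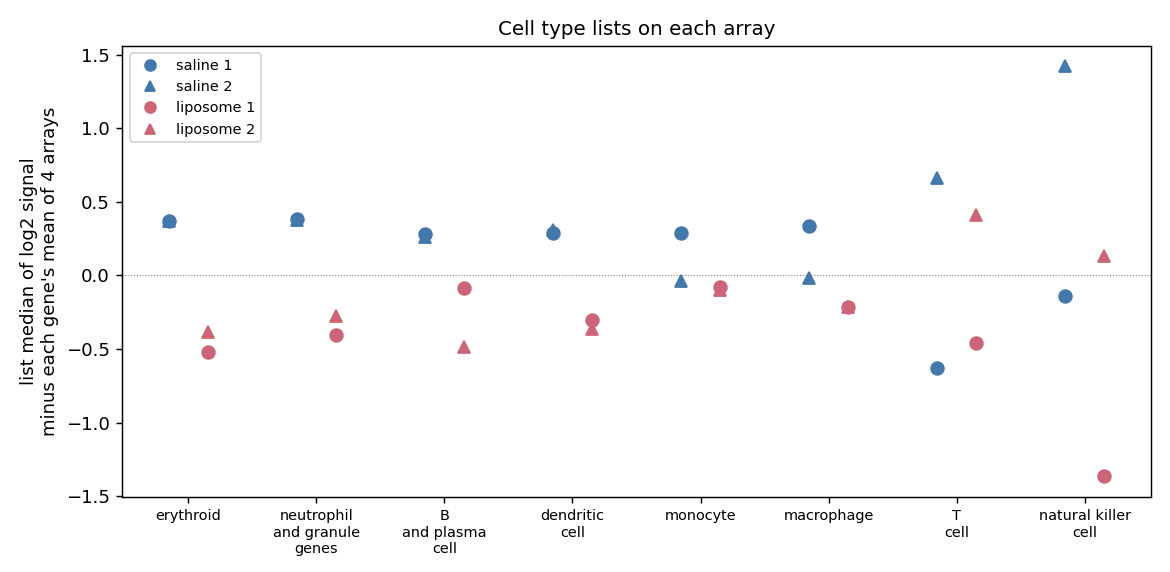
Median over each list's genes of the log2 signal on an array minus the gene's mean over the 4 arrays, for 8 cell type lists (blue saline, red liposome, circle number 1, triangle number 2). For erythroid genes the liposome arrays lie at -0.52 and -0.38 and the saline arrays both at 0.37, while the natural killer medians run from -1.37 on liposome 1 to 1.42 on saline 2.

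Few genes of the remaining cell types passed. Of 7 measured platelet and megakaryocyte markers 1 rose, 1 fell and 5 did not pass (1 rose and 2 fell when adjusted over the list alone), with a median of -0.09. The chemokine gene Pf4 rose 4.30-fold and the platelet glycoprotein gene Gp9 fell 1.99-fold (limma adjusted p = 0.00955 and 0.0198), and Gp1bb and F2rl2 had log2 fold changes of -0.58 and -0.76. Among 18 measured mast cell, basophil and eosinophil markers the eosinophil receptor gene Ccr3 alone fell, over all genes and when adjusted over the list alone (4.57-fold, limma adjusted p = 0.0163), and Hdc lay at -0.77. Of 13 measured progenitor markers Dntt, terminal transferase, rose 7.18-fold (log2 2.84, and 1.74 with normexp) and Flt3 fell, over all genes and when adjusted over the list alone (limma adjusted p = 0.00752 and 0.0267), with a median of -0.32, a mean of -0.06 and camera's direction up. Of 10 measured stromal and endothelial markers Kdr alone fell, over all genes and when adjusted over the list alone (2.22-fold, limma adjusted p = 0.0398, and 0.0533 with median scaling). None of these lists was called by limma's camera (adjusted p = 0.713, 0.103, 0.936 and 0.492 in the order given), except the mast cell, basophil and eosinophil list with median scaling, without saline 1 and without liposome 2 (adjusted p = 0.044, 0.000223 and 0.00748).

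Interferon response genes and immediate early genes lay lower on the liposome arrays. All 31 measured interferon genes had negative log2 fold changes, 4 fell and 27 did not pass (9 fell when adjusted over the list alone), with a median of -0.50 (limma's camera, adjusted p = 5.55e-06, and adjusted p = 0.866 with an estimated correlation). The median difference was -0.86 within title number 1 and -0.22 within number 2. Relative to each gene's mean, the list's median was 0.54 on saline 1, 0.01 on saline 2, -0.32 on liposome 1 and -0.22 on liposome 2, and the median log2 fold change was -0.25 without saline 1 and -0.85 without saline 2. Isg15 and Ifit3, which respond to type I interferon, fell 2.52-fold and 2.36-fold, Irf1 1.88-fold and Gbp5 1.76-fold (limma adjusted p = 0.0459, 0.0412, 0.0308 and 0.0448). Isg15 missed the threshold with quantile normalization (0.0539) and Gbp5 with the mean of a gene's probes (0.0536). Of 21 measured immediate early genes 5 fell, 0 rose and 16 did not pass (8 fell and 1 rose when adjusted over the list alone), with a median of -0.44, and of -0.26 without liposome 1 (limma's camera, adjusted p = 0.00115, and adjusted p = 0.866 with an estimated correlation). Fosl1 fell 2.41-fold, Nr4a1 2.23-fold, Klf2 2.12-fold and Nr4a2 1.74-fold (limma adjusted p = 0.0152, 0.0371, 0.0361 and 0.0278), and the fifth, Btg2, was picked after its value was seen (log2 -0.75). The erythroid and neutrophil lists, with medians of -0.84 and -0.73, lay lower on the same arrays.

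Genes of myeloid suppression, arginine metabolism and inflammation gave few calls. Of 19 measured immunosuppressive myeloid genes Lgals3, galectin-3, alone passed, 2.36-fold higher (limma adjusted p = 0.0228), with 1 risen and 2 fallen when adjusted over the list alone and a list median of -0.11 (limma's camera, adjusted p = 0.66). Nos2, inducible nitric oxide synthase, lay at -0.55 ± 0.27 and Arg1, arginase, at 1.10 ± 0.38 log2 units, Arg1 well above background on 1 of 2 saline arrays (limma adjusted p = 0.243 and 0.134). Vegfa, Ptgs2 and Cd274, which encodes PD-L1, lay at -0.74, -0.77 and 0.59 (limma adjusted p = 0.0525, 0.0585 and 0.082). Of 15 measured arginine and nitric oxide genes Ddah1 alone passed, 2.22-fold lower by its brightest probe (limma adjusted p = 0.021), while its other probe lay at 0.29 and the mean of its probes missed the threshold (-0.43, adjusted p = 0.07). In that list 1 rose and 2 fell when adjusted over the list alone, with a median of 0.03 (limma's camera, adjusted p = 0.713). Of 23 measured cytokine and chemokine genes Il1a alone passed, over all genes and when adjusted over the list alone, 7.15-fold higher (limma adjusted p = 0.0151), with a list median of -0.25 (limma's camera, adjusted p = 0.597, and 0.0355 without liposome 2). Il1b and Cxcl10 lay at -0.57 and -1.28 (limma adjusted p = 0.144 and 0.1), and Il12b, not well above background on the liposome arrays, was at least 2.81-fold lower without passing (limma adjusted p = 0.0745), a bound of 1.39 without saline 1 and of 5.67 without saline 2.

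Stress and cell cycle genes showed no list call by limma's camera. Of 17 measured oxidative stress genes Prdx1, a peroxiredoxin, rose 1.93-fold (limma adjusted p = 0.021), with 1 risen and 4 fallen when adjusted over the list alone and a median of -0.15 (camera adjusted p = 0.713). The metallothionein genes Mt1 and Mt2A lay at -0.71 and -0.75 (limma adjusted p = 0.0639 and 0.0646). Of 19 measured unfolded protein and integrated stress response genes Ddit3 alone fell, 1.48-fold (limma adjusted p = 0.0464, and 0.0671 with median scaling), with 0 calls when adjusted over the list alone and a median of -0.16 (camera adjusted p = 0.502). Of 14 measured heat shock genes Hspb1 alone fell, 2.01-fold (limma adjusted p = 0.0198), with 2 risen and 1 fallen when adjusted over the list alone and a median of 0.09 (camera adjusted p = 0.597). Of 31 measured cell cycle genes 0 passed by limma, over all genes or when adjusted over the list alone, with a median of 0.08 (camera adjusted p = 0.252). Tk1, Mcm2, Tyms and Pcna had log2 fold changes of 0.47, 0.44, 0.59 and -0.42 (limma adjusted p = 0.0572, 0.0914, 0.112 and 0.105). Without saline 2 the cell cycle list was called higher (median 0.32, adjusted p = 0.000622), and without saline 1 its median was -0.12.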

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

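The tests on lymphocyte carry-over, on the share of macrophages, on scaling and on even dilution were chosen only after the results they bear on had been seen. Those on natural killer genes outside the fixed list and on vacuolar ATPase subunits were set before the medians of these 2 lists were computed, but the lists were drawn up after the data, with some of their members, had been seen.

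Probes without a gene name entered no gene-level comparison. Among 1972 such probes tested with limma, 64 passed the threshold, 39 higher and 25 lower on the liposome arrays. Here p was adjusted over all passing probes, with or without a gene name. That is a smaller share than the 1143 of 12858 genes tested, in data that the comparisons did not use.

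As lists, lipid and lysosome genes lay higher on the liposome arrays by limma's camera (adjusted p = 0.651 and 0.753 with an estimated correlation). A larger share of otherwise unchanged macrophages would lift macrophage markers together, but 8 of them fell and 4 rose, which argues against that as the whole cause. The lipid list's median stayed between 0.89 and 1.15 under every scaling and background correction run, so the choice among these does not account for the rise. They put the median of all genes only between -0.047 and 0.045, so this test could hardly have come out otherwise. It cannot exclude a scaling error that all of them share. A rise of the lysosomal system as a whole in cells of the liposome group remains a hypothesis. It predicts a rise of vacuolar ATPase subunits, which acidify lysosomes and of which no measured one was in a fixed list. Their median log2 fold change was 0.61, in the predicted direction (limma's camera, adjusted p = 4.81e-06, and adjusted p = 0.296 with an estimated correlation). Of 18 subunits 8 rose and 10 did not pass. A different mix of macrophage types could raise them as well, so they do not decide between these causes. Uptake of liposomes was not measured on these arrays. A change in which macrophage types the beads captured stays open and untested.

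As lists, neutrophil, erythroid, B cell and dendritic cell genes lay lower on the liposome arrays by limma's camera (adjusted p = 0.651 to 0.866 with an estimated correlation), with 0 of 19 B cell markers past the threshold. An even dilution of all other cell types by a larger macrophage share would lower T cell genes about as far, and the tables do not decide this. The T cell median lay above the erythroid median by 1.05 and 0.63 within the title numbers. With an array left out the gap was 0.40 without liposome 2, 0.18 without saline 1, 1.17 without liposome 1 and 1.34 without saline 2. T cell genes were higher on number 2 in both groups, and the left-out fits have the numbers uneven between the groups. Their gaps thus mix number with group and do not bear on dilution alone. With 2 arrays per group and T cell genes that differ widely within a group, even dilution cannot be told apart from the other causes. These are lower numbers of particular cell types or lower expression within them. The sort should remove most of these cells, B cells and dendritic cells by their MHC class II and red cells for want of CD11b/c, while neutrophils carry CD11b.

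Natural killer cell genes lay lower on the liposome arrays without passing the threshold. A general difference in lymphocyte carry-over would move T cell genes alike, but the T cell median lay above the natural killer median by 1.16 and 1.02 within the title numbers and by 0.82 to 1.52 with each array left out, which argues against it as the whole cause. Fewer natural killer cells in the liposome fractions may be the cause, but 26 natural killer receptor and granule genes outside the fixed list had medians of -0.72 and -0.53 within the numbers. That is below the bound of -0.6 set in advance for number 1 and above it for number 2. The median moved from -0.67 to -0.90 without saline 1, -0.15 without saline 2, -0.17 without liposome 1 and -1.12 without liposome 2. These left-out fits have the title numbers uneven between the groups, so they mix number with group and do not measure chance alone. For the fixed list the medians within the numbers were -1.11 and -1.21. A lower number of natural killer cells still cannot be told apart from lower expression within them, or from chance with 2 arrays per group. Among the 26 genes 4 rose, 2 fell and 20 did not pass. Limma's camera gave an adjusted p of 0.76 over 6 lists drawn up after the data were seen. The 4 that rose, Klra17, Klra5, Ly49i7 and Ly49i9, were not higher on saline 2 than on saline 1, unlike the fixed list. Klra17 lay at 1.14 on saline 1 and 0.77 on saline 2. The list thus mixes genes of different patterns, and its median cannot decide on natural killer cells.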

How the results depend on the processing

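The list medians within title numbers and the fit without T and natural killer cell genes were chosen after the data were seen. All 10 lists called by camera kept their calls under each scaling, filter, probe rule and left-out array (10 to 13 lists called), but camera called 0 with an estimated correlation (1 at unadjusted p under 0.05, against 12 with the preset one) and fry called 6, of which 5 were shared and the progenitor list was not. Lost by fry were the neutrophil, interferon, immediate early, B cell and MHC class II lists (fry adjusted p = 0.0622, 0.27, 0.171, 0.212 and 0.129). Of 1143 genes called by limma, 1064 remained among 1720 with normexp and 1065 among 2028 with a trended robust prior. At an adjusted p under 0.1, 2839 genes passed. Without a filter on dim probes limma called 0 of 21971 genes (3005 at unadjusted p under 0.05). Leaving out 1 array gave 0 to 499 genes, with fewer samples for the spread and the lone array assumed to vary like the other group, and 615 to 758 separated genes against 429. No named gene changed direction in any setting run. Separated genes numbered 243 with normexp and 100 at 4-fold. Without the T and natural killer cell lists 1194 genes passed. Dim signal limits 52 called genes not well above background on either saline array and 36 on either liposome array. The cause of the other shifts was not tested.

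The same title number gave deviations from the group means that correlated at 0.355 across genes (0.332 without T and natural killer genes), but the titles give only "exp" and the number, the labels do not say what it marks, and 2 pairs cannot show pairing. With the number as a block limma called 1816 genes (828 higher, 988 lower), 1120 of them shared, and camera called 11 lists, the natural killer list among them (adjusted p = 1.2e-05, against 4.62e-05 to 0.609 with 1 array left out, and 0.0143 to 0.0483 under other scalings and filters). The block with slide or scan was not run, as there was 1 of each.

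The test's direction turned only for lists without a call at the preset correlation, and the cause was not tested. Median log2 fold changes there were, for progenitor markers, -0.22 with normexp, -0.24 with median scaling, and -0.32 with the filter on all arrays or the block. The T cell median was -0.076 without a filter. With fry, heme and iron stood at 0.083, macrophage markers at -0.43 and arginine genes at 0.035. With each array left out in turn, medians ran from 0.038 to 0.13 for heme and iron, -0.0048 to 0.11 for arginine genes, -0.60 to -0.037 for cytokines, -0.24 to -0.07 for oxidative stress, -0.31 to 0.072 for phagocytic receptors, -0.12 to 0.32 for cell cycle, -0.64 to 0.55 for T cells, -0.63 to 0.015 for mast cells and -0.23 to -0.11 for progenitors.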

Other observations

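The gene groups here were chosen after the values of some of their members had been seen, so their tests are not independent of the choice. Camera's adjusted p-values are over the 6 such lists with at least 5 measured genes.

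Formyl peptide receptor genes, which sense bacterial and mitochondrial peptides, were lower on the liposome arrays. All 3 measured members fell, with log2 fold changes of -3.52 for Fpr3, -2.60 for Fpr1 and -2.56 for Fpr2l (limma adjusted p = 0.00769, 0.00752 and 0.019). With 3 genes they were too few for a list test. Markers of neutrophils and monocytes, which also express these receptors, had medians of -0.73 and -0.15 on the same arrays, with 10 of 19 and 4 of 18 fallen. Of 18 complement components and regulators 8 fell, 0 rose and 10 did not pass, with a median log2 fold change of -0.48 (limma's camera, adjusted p = 1.55e-05, and adjusted p = 0.241 with an estimated correlation). The C1q chain genes C1qa, C1qb and C1qc had log2 fold changes of -1.73, -1.71 and -2.09 and C3 of -1.31 (limma adjusted p = 0.021, 0.0243, 0.0185 and 0.0357). The median stayed between -0.65 and -0.40 under every scaling and with each array left out. On the same arrays the neutrophil, erythroid and macrophage marker lists had medians of -0.73, -0.84 and -0.43. Among 8 metalloproteinases 3 rose (Mmp12, Mmp14 and Mmp7), Mmp8 fell and 4 did not pass (limma's camera, adjusted p = 0.141).

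Of 18 measured vacuolar ATPase genes 8 rose, 0 fell and 10 did not pass. The catalytic subunit gene Atp6v1a rose by 1.35 and Atp6v1d by 1.58 log2 units (limma adjusted p = 0.0267 and 0.0137). Erythroid and neutrophil markers had medians of -0.84 and -0.73 on the same arrays.

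Some genes of amino sugar breakdown rose. Of 17 breakdown genes 8 rose, 0 fell and 9 did not pass, with a median log2 fold change of 0.46 (limma's camera, adjusted p = 1.85e-06, and adjusted p = 0.296 with an estimated correlation). Npl, which splits sialic acid, rose by 2.07, Renbp by 2.03, Gnpda1 by 1.87 and Amdhd2 by 1.83 log2 units (limma adjusted p = 0.0255, 0.00837, 0.016 and 0.0149). The hypothesis of a rise of breakdown apart from synthesis was left undecided. Of 8 synthesis genes 2 rose, Uap1l1 by 2.29 and Pgm3 by 1.13, with a median of 0.18 (limma's camera, adjusted p = 0.0721), and the breakdown median lay 0.28 above it, just under the difference of 0.3 asked for. This difference was 0.48 and 0.47 within the title numbers, 0.28 to 0.36 under other scalings and normexp, and 0.53, 0.46, 0.25 and 0.34 without saline 1, saline 2, liposome 1 and liposome 2, so it lay above 0.3 in most settings and below it in others.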
